A study of Mus musculus with 12 samples.

How the data were processed

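RNA of S100β-v-erbB/p53-/- TSC1 mouse cells of the FVB-NJ strain was profiled on Clarion S mouse arrays, with 4 groups of 3 arrays (normoxia with DMSO, hypoxia with DMSO, hypoxia with BFA and hypoxia with EHT-1864). Per the labels, cells were grown in DMEM F-12 with B27 supplement and exposed for 16 h, RNA was extracted with Trizol and labelled with a WT Plus kit. Per the labels' design text, 3 independent cultures were used, but the labels do not say whether arrays with the same number share a culture. Groups and array numbers were taken from the sample labels. The labels give the BFA dose as 1 µM in the treatment protocol and design text and as 0.1 µM in the series title, and this was not settled here.

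The deposited values were on the log2 scale, with 1 value per transcript cluster and array. Per the submitters' processing notes, the authors made them by RMA in Affymetrix Expression Console. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of a transcript cluster, and it pulls the distributions of the arrays towards each other, so a change in total RNA per cell is not visible in such values. The versions, the RMA settings and the genome build were not given in the sources used here, so no coordinates are given. The value table held 28846 rows, of which 6640 were controls (5222 neg, 1324 pos, 4 hybridization and 4 poly-A among them) and were left out of the tests. The remaining 22206 transcript clusters are called probes here, and all were tested without a filter on level. Signal over background was judged from the 95th percentile of the neg control probes of each array. The number of arrays limits the precision.

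Probes were named through the platform annotation, with symbols updated by Entrez number through a gene table of assembly GRCm38.p6. Of the probes, 19572 had 1 symbol (all matched), 0 had several and 2634 had none given. For genes with several probes, the probe with the highest mean over all arrays stood for the gene, which gave 19505 genes. Called probes of the same gene had opposite signs for 0 genes in hypoxia against normoxia, 2 for BFA, 2 for EHT-1864 and 1 between the compounds, out of 55 genes with several probes.

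All 12 arrays were fitted together with limma (lmFit and eBayes, with no trend and no robust setting), so that the groups shared 1 estimate of the spread (residual df 8, prior df 4.87). The comparisons were hypoxia against normoxia with DMSO, BFA and EHT-1864 each against DMSO in hypoxia, and BFA against EHT-1864. Each compound in hypoxia was also set against normoxia. Adjusted p values are those of Benjamini and Hochberg over all probes of a comparison, with a threshold of 0.05, and confidence is given as the standard error of the fit. The p values measure the spread between the arrays of a group, which may be partly technical. A gene below the floor on all 3 arrays of a group was given a bound, the mean of the brighter group minus the mean, over the arrays of the dim group, of the higher of the floor and the measured value. No fold was given where both groups were below the floor.

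Shifts of 25 gene lists were tested with camera of limma (preset correlation 0.01), adjusted over the lists of a comparison. They covered HIF-1 targets, glycolysis, oxidative phosphorylation, ER chaperones and ERAD, ATF4 and the integrated stress response, Golgi with COPI and ARF, COPII, cholesterol synthesis, Rac and actin nucleation, SRF and YAP targets, ERK output, G2/M, G1/S, glioma stem cells, invasion with matrix and mesenchymal genes, NF-kB and cytokines, interferon response, autophagy and lysosome, ribosomal proteins, and markers of astrocytes, the oligodendrocyte lineage, neurons, microglia and macrophages, endothelial cells, and fibroblasts and pericytes. Of 562 list members, 518 were measured. Each list was also tested with an estimated correlation and with fry, and its median was placed among 10000 random lists matched on mean level (within 100 ranks). Genes raised or lowered by hypoxia were counted under the compounds, and overlaps of comparisons that share the hypoxia DMSO arrays were set beside 100 simulated draws of unchanged groups.

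The groups, comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. By that rule the genes named were, per comparison, the 8 largest rises and 8 largest falls among probes past the threshold whose 3 arrays of a group all lay above or below those of the other, with 1 symbol and without predicted or unnamed symbols, the 3 members with the smallest adjusted p in each called list, and 16 fixed genes, of which 14 were measured. Genes of the first kinds whose function was unsure were left out of the text.

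The alternatives were another quantile normalization of the deposited values, subtraction of each array's median, leaving out the dimmest 25% of probes, a log2 value of at least 6 on at least 3 arrays, a trended and robust variance model, array weights, a fit of the 6 compared arrays alone, the array number as a block, 1 probe per gene, a log2 change of at least 1, an adjusted p under 0.01, camera with an estimated correlation, fry, and leaving out each of the 12 arrays. A filter on the 95th percentile of the neg controls was added after the data were seen. When an array was left out, the remaining arrays of its group were taken to vary like those of the other groups.

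The fit was tested on simulated data of 22206 probes. A log2 change of 0.5 was recovered for 20.9% of the changed probes in hypoxia against normoxia, 14.9% for BFA, 13.4% for EHT-1864 and 7.46% between the compounds, a change of 1 for 88.1%, 85.1%, 88.1% and 82.1%, and a change of 2 for 100% in each, with 5, 8, 10 and 4 false calls. Only 66 or 67 probes were changed at each size, while 11269 of 22206 real probes were called for BFA. Adjusted p values are harder to pass when so few probes change, so these shares do not give the sensitivity of the real comparisons. Their differences at 0.5 rest on few probes (14, 10, 9 and 5 recovered of 67). Within groups the arrays correlated at r = 0.979 to 0.995 across probes and between groups at 0.933 to 0.989, and the first principal components held 53.9% and 19.2% of the variance. The work used R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.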

Results

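Gene expression was measured in cultures of S100β-v-erbB/p53-/- TSC1 mouse cells of the FVB-NJ strain. The v-erbB oncogene encodes an active receptor tyrosine kinase related to the epidermal growth factor receptor, and mice carrying it under the S100β promoter are used as a glioma model. Cultures were kept for 16 h in normoxia with the solvent DMSO, in hypoxia with DMSO, in hypoxia with brefeldin A (BFA), or in hypoxia with EHT-1864. Brefeldin A blocks transport from the endoplasmic reticulum (ER) to the Golgi by acting on exchange factors of ARF GTPases, and EHT-1864 is an inhibitor of Rac GTPases. The EHT-1864 dose was 1 µM, and the labels give the BFA dose both as 1 µM and as 0.1 µM, so the BFA values belong to a dose that was either of these. Each of the 4 groups held 3 arrays, 12 in all, and this number of arrays limits the precision.

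Values were log2 signals of 22206 probes (transcript clusters), and in the text below "±" after a log2 change gives its standard error from the limma fit, with n = 3 arrays in each group. The median log2 value of an array lay between 5.35 and 5.46. The arrays of the compound groups had a narrower spread of values than the DMSO arrays. The SD of the log2 values over all probes averaged 2.48 in normoxia, 2.51 in hypoxia with DMSO, 2.28 with BFA and 2.41 with EHT-1864. The hybridization control probes, which detect transcripts added to the hybridization mix and not RNA of the cells, averaged 9.76 ± 0.06 (SD, n = 3) in hypoxia with DMSO, 10.93 ± 0.12 with BFA and 10.25 ± 0.07 with EHT-1864. The share of probes below the 95th percentile of the neg control probes of their array averaged 51.7% in hypoxia with DMSO, 65.2% with BFA and 57.6% with EHT-1864. These shifts went along with every comparison that involves BFA or EHT-1864. This 95th percentile served as the floor. A gene below the floor on all 3 arrays of a group was too dim there for a fold change, and it is given as a lower bound ("at least N-fold") of the other group's mean against the floor of the dim group. Where only some arrays of a group lay above the floor, their number is given.

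**Figure D1:**
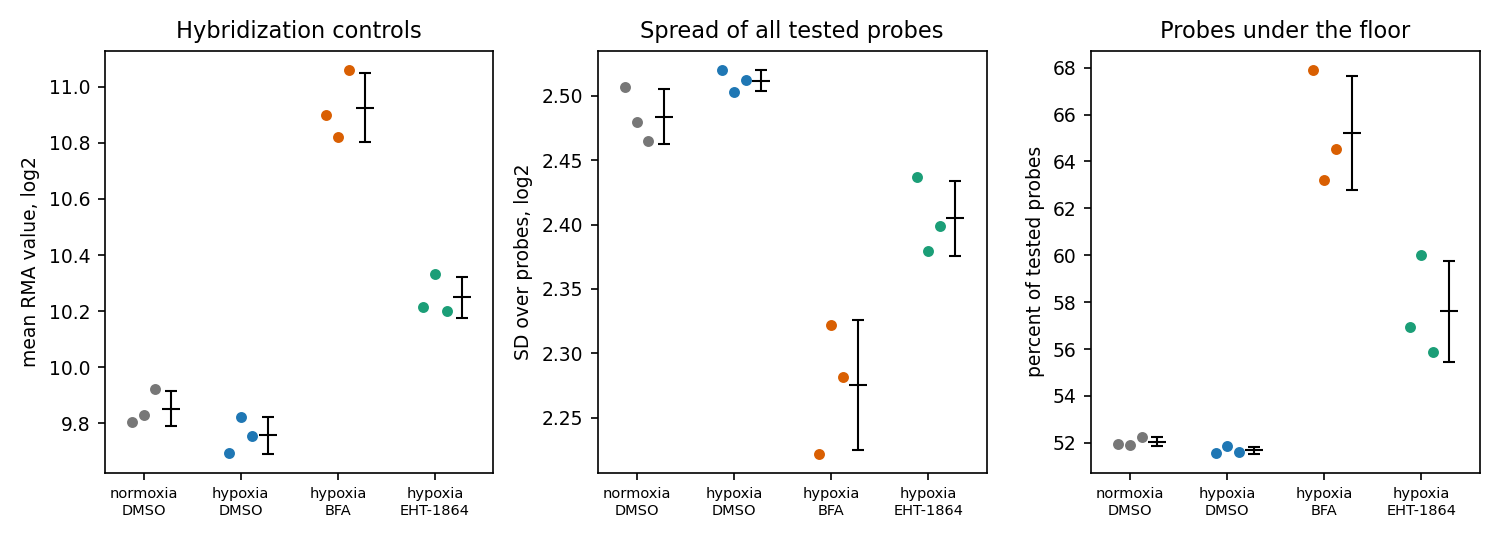
Points are single arrays and black bars show the mean ± SD (n = 3) of the 4 hybridization control probes (mean log2 value), of the SD of the log2 values over all 22206 probes, and of the percentage of these probes under the floor, which is the 95th percentile of the neg control probes of the array. The hybridization controls averaged 9.76 in hypoxia with DMSO, 10.93 with BFA and 10.25 with EHT-1864, and the vertical axes do not start at 0.

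The first comparison asked which genes differed between hypoxia and normoxia in DMSO-treated cells. Hypoxia raised genes of the HIF-1 response and of glycolysis. P4ha2, a subunit of the collagen prolyl 4-hydroxylase, rose by 4.05 ± 0.15 on the log2 scale (16.6-fold, limma adjusted p = 1.53e-08), from 6.24 ± 0.02 to 10.29 ± 0.11 (mean ± SD). Ndrg1, a stress-induced gene, rose by 4.01 ± 0.16, and Pdk1, the kinase that inhibits pyruvate dehydrogenase, rose by 3.86 ± 0.25. The angiogenic factor Vegfa rose by 3.09 ± 0.20 (adjusted p = 1.01e-06), the glucose transporters Slc2a3 and Slc2a1 by 3.56 ± 0.18 and 2.34 ± 0.14, and the HIF prolyl hydroxylase Egln3 by 3.33 ± 0.17. Lower bounds were at least 12.95-fold for Ankrd37 (adjusted p = 1.53e-08), at least 6.21-fold for the glycogen regulator Ppp1r3c (adjusted p = 2.05e-08), at least 3.18-fold for the lactate transporter Slc16a3 (adjusted p = 8.85e-06) and at least 2.88-fold for the carbonic anhydrase Car9 (adjusted p = 5.75e-06).

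Of 31 measured HIF-1 target genes, 26 rose, none fell and 5 did not pass, and 27 rose when adjusted over the list alone (median log2 change 2.21, camera adjusted p = 7.35e-63). Of 16 measured glycolysis genes, 15 rose and 1 did not pass, and 16 rose when adjusted over the list alone (median 1.41, camera adjusted p = 2.21e-40). Among them, the phosphofructokinase Pfkl rose by 2.28 ± 0.13 and the triosephosphate isomerase Tpi1 by 2.41 ± 0.15. Of 26 genes of ATF4 and the integrated stress response, 16 rose and 10 did not pass, and 20 rose when adjusted over the list alone (median 0.69, camera adjusted p = 3.86e-27). Examples were the stress regulator Nupr1 at 2.28 ± 0.17, the lipoprotein receptor Vldlr at 2.01 ± 0.17 and the cystine transporter Slc7a11 at 2.03 ± 0.18, and the stress transcription factor Ddit3 rose by 1.74 ± 0.16. These 3 lists were also called with an estimated correlation (adjusted p = 0.00128, 0.00964 and 0.0496). The ER chaperones and ERAD list was not called (median −0.01, mean 0.01, which differ in sign), and its member Hspa5, the chaperone BiP, differed by −0.12 ± 0.10 (adjusted p = 0.630).

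Cell cycle lists were lower in hypoxia. Of 22 G1/S genes, 4 fell, or 20 when adjusted over the list alone (median −0.53, camera adjusted p = 9.24e-16, adjusted p = 0.05002 with an estimated correlation, which misses the threshold). Mcm3, a subunit of the replicative helicase, fell by 0.66 on the log2 scale (SE 0.11, adjusted p = 0.00598). Of 24 G2/M genes, 1 fell, or 13 when adjusted over the list alone (median −0.38, adjusted p = 0.0842 with an estimated correlation). Among other genes that fell were Sytl2, a synaptotagmin-like protein of vesicle transport, at −1.12 ± 0.18, and Pcolce2, an enhancer of procollagen processing, at −1.10 ± 0.17. Fn1, which encodes the matrix protein fibronectin, rose by 1.18 ± 0.20 (adjusted p = 0.00666) and was 1 of 3 of 24 invasion, matrix and mesenchymal genes that rose (median 0.14, adjusted p = 0.05002 with an estimated correlation, which misses the threshold).

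In the lists with smaller shifts called by camera, few or no members passed by themselves. The Golgi, COPI and ARF list rose (3 of 34 genes, median 0.11, adjusted p = 0.329 with an estimated correlation), with median 0.17 without hypoxia DMSO array 2, led by Kdelr3, a receptor that returns ER proteins from the Golgi, at 2.09 ± 0.13. The COPII list (1 of 19 genes, median 0.12, adjusted p = 0.201 with an estimated correlation) and the cholesterol synthesis list (1 of 20 genes, 7 when adjusted over the list alone, median 0.21, adjusted p = 0.161 with an estimated correlation) were also called higher. None of 29 oxidative phosphorylation genes passed by itself while the list was called lower (median −0.18, camera adjusted p = 6.17e-04, adjusted p = 0.161 with an estimated correlation). The ribosomal protein list (0 of 18 genes, median 0.09) was called higher and the oligodendrocyte lineage list (1 of 16 genes fell, median −0.19) lower, each with adjusted p = 0.312 with an estimated correlation. The call of the ribosomal list ended without hypoxia DMSO array 2 (adjusted p = 0.102) or normoxia array 2 (0.106), and after median subtraction (0.0610). That of the oligodendrocyte list ended without hypoxia DMSO array 1 (0.0810), normoxia array 1 (0.0645) or normoxia array 2 (0.0709), and after quantile normalization (0.0637). Among probes with a log2 value of at least 6 on at least 3 arrays the COPII and ribosomal lists (0.104 each) and the oligodendrocyte list (0.184) were not called. Among probes above the floor on at least 3 arrays, a filter chosen after the data were seen, the same lists were not called (0.125, 0.125 and 0.197). With the dimmest 25% of probes left out, the ribosomal and oligodendrocyte calls ended as well (0.0511 and 0.0533).

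Several genes fixed in advance did not pass in hypoxia against normoxia. The log2 differences were 0.12 ± 0.13 for Hif1a, which encodes the oxygen-regulated subunit of HIF-1, −0.05 ± 0.11 for Rac1, 0.02 ± 0.11 for Arf1 and 0.20 ± 0.13 for Gbf1, an ARF exchange factor. They were 0.25 ± 0.13 for Sox2, −0.19 ± 0.11 for Olig2 and −0.01 ± 0.18 for Nes, which are stem and progenitor cell genes. Egfr was below the floor on all 12 arrays (group means 3.95 to 4.36), and Epas1, which encodes HIF-2α, was above it on 1 array of hypoxia with DMSO and on no other (group means 4.48 to 5.37). In all, 593 of 22206 probes passed in limma, 468 higher and 125 lower in hypoxia, and 175 of these differed at least 2-fold (171 higher, 4 lower). The count fell to 273, 287 and 284 without hypoxia DMSO array 1, 2 or 3 and to 315, 282 and 254 without normoxia array 1, 2 or 3, and it rose to 898 without BFA array 1. Without any 1 of the 6 arrays compared, 228 to 291 probes in place of 468 passed as higher and 23 to 28 in place of 125 as lower. It was 1221 with a trended, robust variance model, and Ccne1, a cyclin of the G1/S list that fell by 0.87 (adjusted p = 0.0345), did not pass without any 1 of the 6 arrays compared (adjusted p up to 0.147).

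**Figure D2:**
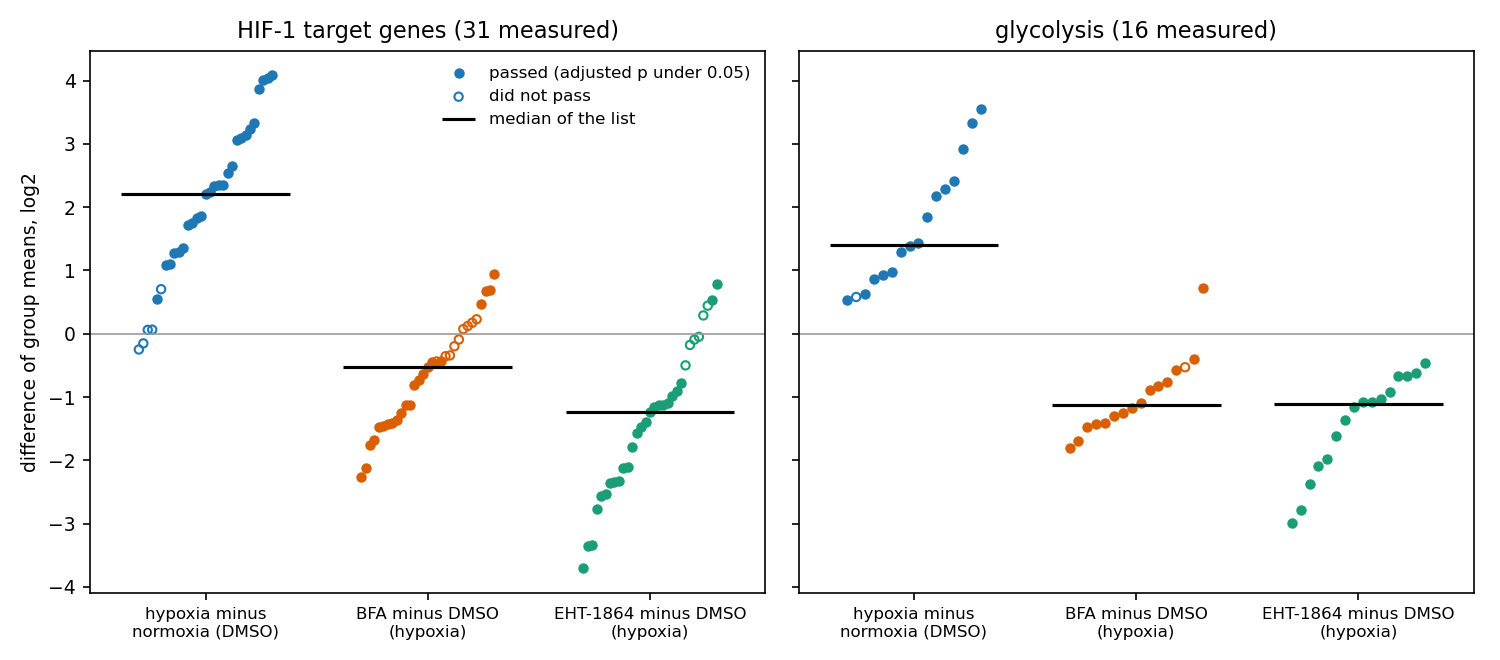
Each circle is a gene of the HIF-1 target list (31 measured) or the glycolysis list (16 measured), placed by its difference of group means on the log2 scale in 3 comparisons, sorted by size within each, with filled circles for genes that passed (limma adjusted p under 0.05) and a black bar for the list median. The HIF-1 median was 2.21 in hypoxia against normoxia, −0.52 with BFA and −1.24 with EHT-1864, and the glycolysis median was 1.41, −1.13 and −1.12.

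The next comparison asked what BFA changed in hypoxia. Genes of protein folding and transport in the ER and Golgi rose and cholesterol synthesis, cell cycle and progenitor genes fell. Fgf21, a hormone gene induced by the integrated stress response, rose by 5.88 ± 0.25 on the log2 scale (limma adjusted p = 4.38e-09), and in the DMSO group it was above the floor on 1 of 3 arrays. The stress transcription factors Atf3 and Ddit3 rose by 3.07 ± 0.13 and 2.49 ± 0.16, and a further Ddit3 probe gave 2.69 ± 0.15. The ER chaperone gene Hspa5 rose by 1.27 ± 0.10, from 12.03 ± 0.01 to 13.30 ± 0.05 (mean ± SD, adjusted p = 5.38e-07). It was the brightest probe on each BFA array, and whether its signal was saturated there was not tested. The progenitor transcription factors Olig1 and Olig2 fell by 4.21 (SE 0.16) and by 3.34 (SE 0.11), the latter from 11.44 ± 0.01 to 8.10 ± 0.12 (mean ± SD, adjusted p = 1.06e-09).

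Of 25 measured ER chaperones and ERAD genes, 22 rose, none fell and 3 did not pass, with the same 22 when adjusted over the list alone (median 1.01, camera adjusted p = 9.60e-12). Derl3 and Dnajb9, which act in ER-associated degradation and folding, rose by 2.56 ± 0.13 and 2.35 ± 0.12, and Creld2, an ER stress gene, rose by 1.90 ± 0.11. Of 19 COPII genes, whose products coat vesicles leaving the ER, 13 rose (13 when adjusted over the list alone, median 0.68), among them Sec23a at 1.10 ± 0.12, Sec22b at 0.97 ± 0.10 and Bet1 at 0.99 ± 0.11. In the Golgi, COPI and ARF list, 20 of 34 genes rose, 3 fell and 11 did not pass, or 21 and 3 when adjusted over the list alone (median 0.41, adjusted p = 0.199 with an estimated correlation). Gbf1 rose by 1.36 ± 0.13, the ER-resident transcription factor Creb3 rose by 1.59 ± 0.13 and its relative Creb3l2 fell by 1.44 (SE 0.13). Arf1 differed by 0.19 ± 0.11 (adjusted p = 0.147). Of 26 ATF4 and integrated stress response genes, 17 rose and 9 did not pass, and 18 rose when adjusted over the list alone (median 0.54, adjusted p = 0.199 with an estimated correlation).

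All 20 measured cholesterol synthesis genes fell, also when adjusted over the list alone (median −1.12, camera adjusted p = 9.38e-11). The HMG-CoA synthase Hmgcs1 fell by 2.29 (SE 0.12), the sterol dehydrogenase Nsdhl fell by 2.36 (SE 0.13), and Hsd17b7, an enzyme of the same pathway, was at least 3.36-fold lower (adjusted p = 1.87e-09). Of 24 G2/M genes, 23 fell, or 24 when adjusted over the list alone (median −1.06), with cyclin A2 (Ccna2) at −1.83 ± 0.13 and the spindle protein Nusap1 at −1.53 ± 0.10. Of 22 G1/S genes, 19 fell, also when adjusted over the list alone (median −1.15, adjusted p = 0.0954 with an estimated correlation), with the helicase subunit Mcm6 at −2.01 ± 0.13 and the ribonucleotide reductase subunit Rrm1 at −1.57 ± 0.13. Of 30 Rac and actin nucleation genes, 21 fell, or 24 when adjusted over the list alone (median −0.70), with Arpc1b, a subunit of the Arp2/3 complex, at −1.58 ± 0.11 and the WAVE protein Wasf1 at −1.88 ± 0.14. Rac1 fell by 0.47 (SE 0.11).

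In the ERK pathway output list, 15 of 21 genes fell and 4 rose, also when adjusted over the list alone (median −1.44). The ETS factors Etv1 and Etv5, which are induced by ERK signalling, fell by 2.69 (SE 0.14) and by 1.97 (SE 0.12), and Phlda1 was at least 5.10-fold lower (adjusted p = 4.34e-08). In the glioma stem cell list, 12 of 21 genes fell, 2 rose and 7 did not pass, also when adjusted over the list alone (median −0.69). The brain lipid-binding protein gene Fabp7 fell by 2.80 (SE 0.11) and Sox2 by 1.66 (SE 0.13), and Nes differed by −0.05 ± 0.18 (adjusted p = 0.811). In the oligodendrocyte lineage list, 10 of 16 genes fell and 3 rose, also when adjusted over the list alone (median −1.42, adjusted p = 0.0849 with an estimated correlation). The progenitor receptor Gpr17 fell by 4.05 (SE 0.14) and was above the floor on 2 of 3 BFA arrays. Further large falls were those of the proteoglycan Sdc3, at −3.79 ± 0.13, and of the Notch ligand Dll3, at least 9.37-fold, the insulin-like growth factor binding protein Igfbp5, at least 8.02-fold, and the sodium pump subunit Atp1b2, at least 4.88-fold (adjusted p = 1.06e-09, 6.09e-09 and 1.06e-09).

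Genes raised by hypoxia were partly lower with BFA. Of 31 HIF-1 target genes, 18 fell, 4 rose and 9 did not pass, or 19 and 4 when adjusted over the list alone (median −0.52, adjusted p = 0.199 with an estimated correlation). Of 16 glycolysis genes, 14 fell, 1 rose and 1 did not pass, or 15 and 1 when adjusted over the list alone (median −1.13, adjusted p = 0.142 with an estimated correlation). Egln3 fell by 2.26 (SE 0.17), the adenylate kinase Ak4 fell by 1.76 (SE 0.14), Tpi1 fell by 1.81 (SE 0.15), the phosphofructokinase Pfkm fell by 1.43 (SE 0.11), and Hif1a itself fell by 1.03 (SE 0.13). Vegfa differed by −0.36 ± 0.20 (adjusted p = 0.152) and Slc2a1 by −0.34 ± 0.14 (adjusted p = 0.0555), and Car9 was at least 1.56-fold lower (adjusted p = 2.49e-05). In the invasion, matrix and mesenchymal list, 13 of 24 genes fell and 3 rose, or 14 and 3 when adjusted over the list alone (median −0.43, adjusted p = 0.0849 with an estimated correlation). The matrix protein gene Tnc fell by 1.85 (SE 0.16, 2 of 3 BFA arrays above the floor) and the cadherin gene Cdh2 fell by 1.79 (SE 0.17). The NF-kB and cytokine list was called higher, with 10 of 19 genes up and 2 down, also when adjusted over the list alone (median 0.48, camera adjusted p = 0.0312, adjusted p = 0.0849 with an estimated correlation), although 14 members were under the floor in both groups. Ptgs2, which encodes cyclooxygenase-2, was at least 2.56-fold higher (adjusted p = 2.41e-07), and the NF-kB inhibitor Nfkbia was at least 1.64-fold lower (adjusted p = 1.86e-04).

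Lists that were not called with BFA were oxidative phosphorylation (median −0.22), SRF and YAP target genes (7 of 21 rose and 9 fell), interferon response (median −0.01), autophagy and lysosome (median 0.23, camera adjusted p = 0.0544), ribosomal proteins (median −0.08) and the markers of astrocytes (median −0.39, camera adjusted p = 0.0544), neurons (0.25), microglia and macrophages (0.28), endothelial cells (0.45) and fibroblasts and pericytes (0.18). Of these marker genes, 12 of 13 for microglia, 11 of 12 for endothelial cells, 11 of 15 for neurons and 9 of 11 for fibroblasts were under the floor in both groups. After quantile normalization the autophagy list was called higher (median 0.50, adjusted p = 4.94e-05) and the astrocyte list lower (−0.61, 0.0152), and the medians of the oxidative phosphorylation, ribosomal and fibroblast lists turned to 0.05, 0.09 and −0.15, without a call. The autophagy list was also called with every filter on level (adjusted p = 3.63e-04 to 0.0174), with a trended, robust model (0.0197), with array weights (0.0394), and without hypoxia DMSO array 1 (0.0340) or BFA array 1 (0.0222). The astrocyte list was called with array weights (0.0463), with the 6 compared arrays alone (0.0437) and without BFA array 1 (0.0369). The oxidative phosphorylation list was called lower with a trended, robust model (0.0434) and without hypoxia DMSO array 1 (0.0474) or BFA array 2 (0.0438), and the endothelial list higher without BFA array 3 (0.0319). The medians of the SRF and YAP and the interferon lists turned to 0.07 each after median subtraction, without a call. With an estimated correlation the calls of the ER, COPII, cholesterol, Rac, G2/M, ERK and glioma stem cell lists held (adjusted p = 0.0264 to 0.0422).

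In limma, 11269 of 22206 probes passed for BFA against DMSO in hypoxia, 5799 higher and 5470 lower. Of these, 3235 differed at least 2-fold (947 higher, 2288 lower), and 4326 of the 11269 were under the floor in both groups. When only probes with a log2 value of at least 6 on at least 3 arrays were tested, 7215 passed and 30.5% of these were higher, against 51.5% before, and the calls of the HIF-1 (adjusted p = 0.0839), ERK (0.0557), invasion (0.253) and NF-kB (0.379) lists ended. These calls also ended among probes above the floor on at least 3 arrays (adjusted p = 0.0652, 0.0629, 0.289 and 0.274), and the NF-kB median turned to −0.46 and −0.14 with these filters. Quantile normalization across the arrays ended the NF-kB call as well (0.0872) and moved the medians of the HIF-1 list to −0.23, the Rac list to −0.39, the glioma stem cell list to −0.41 and the Golgi list to 0.68, all still called. Over the members left by the filter at a log2 value of 6, the medians were −1.66 for the glioma stem cell list, −2.72 for the oligodendrocyte list (both still called) and −0.72 for the invasion list. Over those above the floor on at least 3 arrays they were −1.61, −2.72 and −0.65, and the oligodendrocyte median was −2.60 with the dimmest 25% of probes left out. These totals went along with hybridization controls 1.17 higher on the BFA arrays.

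**Figure D3:**
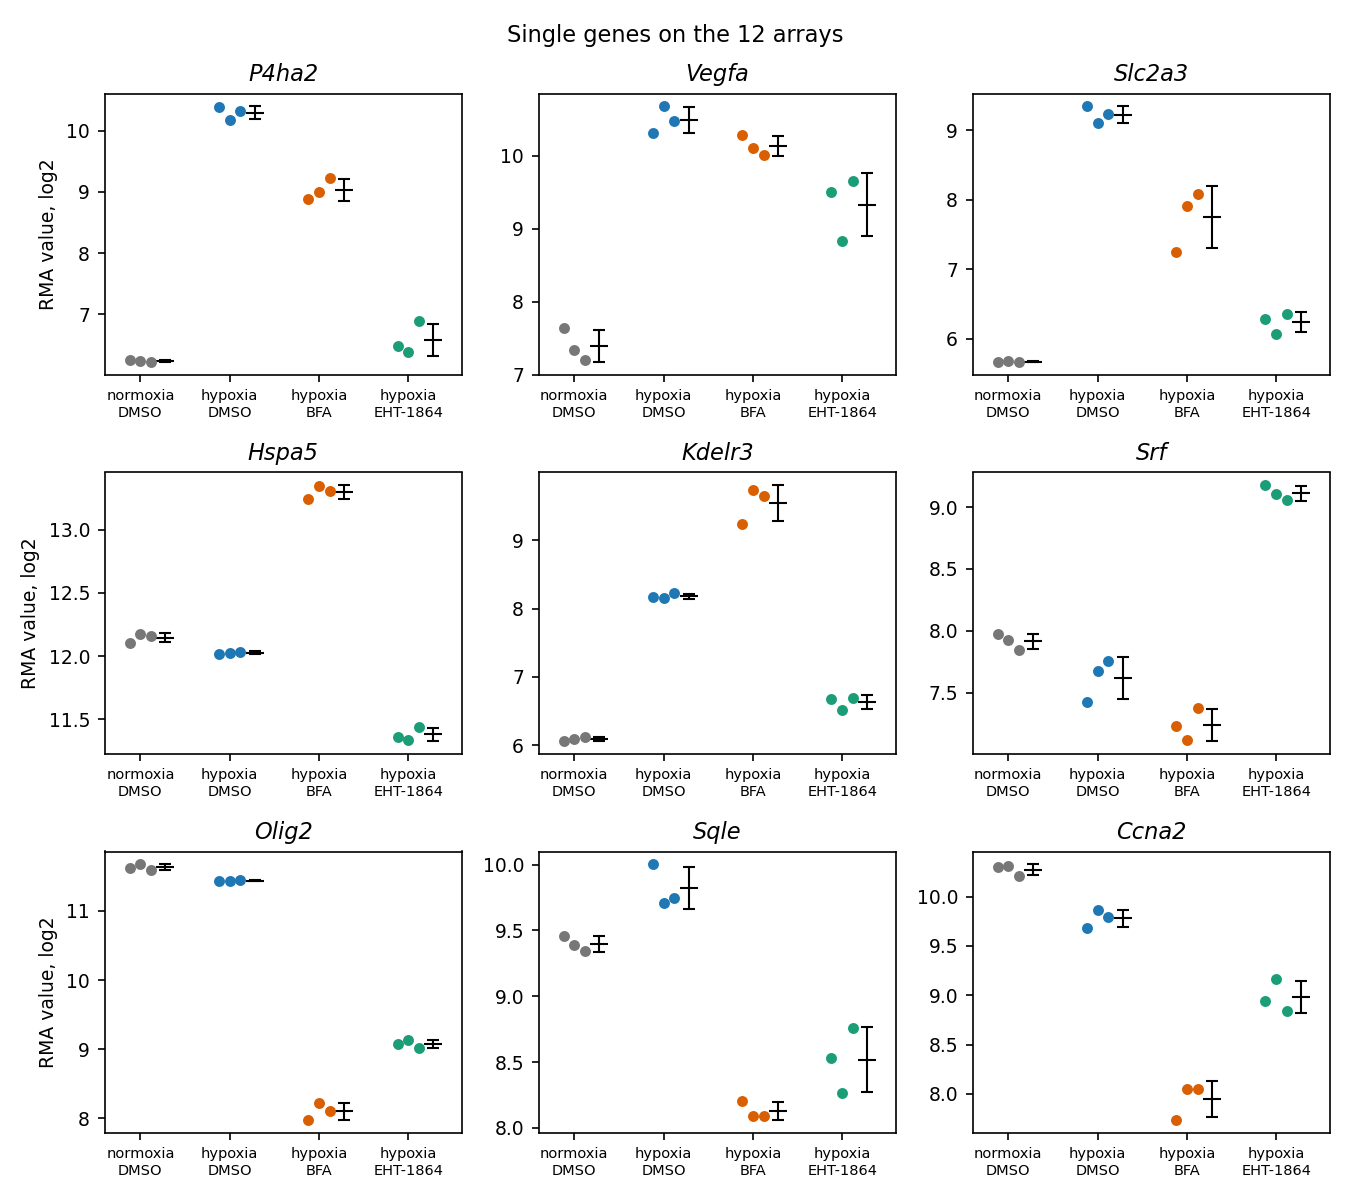
Points are the log2 values of 9 genes on the single arrays of the 4 groups, and black bars show the mean ± SD (n = 3) of each group. P4ha2 and Vegfa rose in hypoxia and were lowest among the hypoxia groups with EHT-1864, Hspa5 averaged 13.30 with BFA and 11.38 with EHT-1864, and Olig2 averaged 11.44 in hypoxia with DMSO, 8.10 with BFA and 9.08 with EHT-1864 (the vertical axes do not start at 0).

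A further comparison asked what EHT-1864 changed in hypoxia. Many genes raised by hypoxia were lower with the compound. P4ha2 fell by 3.70 (SE 0.15) on the log2 scale (limma adjusted p = 2.33e-08), to 6.59 ± 0.26 (mean ± SD) against 10.29 ± 0.11 with DMSO. Ankrd37 fell by 3.35 (SE 0.16), Pdk1 by 3.34 (SE 0.25), Slc2a3 by 2.99 (SE 0.18), Vegfa by 1.16 (SE 0.20) and Slc2a1 by 0.98 (SE 0.14). Of the 3 EHT-1864 arrays, 1 was above the floor for Ankrd37 and 2 for Pdk1 and Slc2a3. Car9 was at least 2.19-fold lower (adjusted p = 5.52e-06). Hif1a differed by −0.13 ± 0.13 (adjusted p = 0.486) and Rac1 by 0.02 ± 0.11 (adjusted p = 0.918), and neither passed.

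Of 31 HIF-1 target genes, 23 fell, 2 rose and 6 did not pass, or 24 and 2 when adjusted over the list alone (median −1.24, camera adjusted p = 6.01e-14). The mitochondrial protein gene Fam162a fell by 2.54 (SE 0.13). All 16 glycolysis genes fell, also when adjusted over the list alone (median −1.12, adjusted p = 0.0819 with an estimated correlation), with Pfkl at −2.09 ± 0.13 and the phosphoglycerate mutase Pgam1 at −1.62 ± 0.12. Of 20 cholesterol synthesis genes, 14 fell, or 16 when adjusted over the list alone (median −0.45, adjusted p = 0.139 with an estimated correlation), with Hmgcs1 at −1.15 ± 0.12 and the squalene epoxidase Sqle at −1.30 ± 0.14. Of 29 oxidative phosphorylation genes, 8 rose and 1 fell, also when adjusted over the list alone (median 0.22, adjusted p = 0.227 with an estimated correlation), with Ndufb5, a complex I subunit, at 0.75 ± 0.11.

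Target genes of SRF and YAP, which respond to the actin cytoskeleton, were higher with EHT-1864. Of 21 measured, 12 rose, 1 fell and 8 did not pass, or 13 and 1 when adjusted over the list alone (median 0.43, camera adjusted p = 2.25e-04). The focal adhesion protein gene Zyx rose by 1.65 ± 0.13, the calponin gene Cnn2 by 2.07 ± 0.20 (2 of 3 DMSO arrays above the floor) and Srf itself by 1.49 ± 0.12. The ERK pathway output list moved down as a whole, with 10 of 21 genes lower and 4 higher, or 11 and 4 when adjusted over the list alone (median −0.47, camera adjusted p = 0.00287). Egr1, an immediate early transcription factor, fell by 2.26 (SE 0.14), Ier3 was at least 3.88-fold lower (adjusted p = 1.75e-07), and Jun rose by 2.18 ± 0.13. The NF-kB and cytokine list moved up, with 6 of 19 genes higher and 1 lower, or 7 and 1 when adjusted over the list alone (median 0.39, camera adjusted p = 0.00195, 14 members under the floor in both groups). Its inhibitor Nfkbia rose by 0.96 ± 0.14 and Ptgs2 was at least 1.85-fold higher (adjusted p = 6.39e-06). Of 23 autophagy and lysosome genes, 10 rose, 2 fell and 11 did not pass, or 11 and 3 when adjusted over the list alone (median 0.23, adjusted p = 0.230 with an estimated correlation), with Gabarapl1 at 1.37 ± 0.11, the autophagy receptor gene Sqstm1 at 0.89 ± 0.10 and the folliculin gene Flcn at 1.25 ± 0.16.

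Secretory pathway lists were called lower with EHT-1864 by camera with the preset correlation. Their medians were not extreme among level-matched random lists, at percentile 6.92 for Golgi, 12.74 for COPII and 7.96 for ER. A shift shared with other probes of the same level was therefore not excluded for these lists. Of 34 Golgi, COPI and ARF genes, 13 fell and none rose, also when adjusted over the list alone (median −0.21, adjusted p = 0.344 with an estimated correlation), with Kdelr3 at −1.55 ± 0.13, Kdelr2 at −0.96 ± 0.10 and Gbf1 at −0.55 ± 0.13. Of 19 COPII genes, 8 fell (8 fell and 1 rose when adjusted over the list alone, median −0.22, adjusted p = 0.225 with an estimated correlation), with Sec23a at −1.02 ± 0.12 and Sec24d at −1.22 ± 0.15. Of 25 ER chaperones and ERAD genes, 9 fell and 2 rose, or 11 and 3 when adjusted over the list alone (median −0.20, camera adjusted p = 0.0276, adjusted p = 0.433 with an estimated correlation), with the ubiquitin ligase Syvn1 at −0.80 ± 0.12 and Hspa5 at −0.65 ± 0.10. After quantile normalization the ER and COPII lists were no longer called (adjusted p = 0.123 and 0.0693). The ATF4 and integrated stress response list was not called (4 rose and 4 fell of 26, median −0.05, mean 0.04, which differ in sign), while its member Ddit3 rose by 1.66 ± 0.16. Arf1 differed by −0.07 ± 0.11 (adjusted p = 0.660).

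In the oligodendrocyte lineage list, 9 of 16 genes fell, 1 rose and 6 did not pass, or 10 and 1 when adjusted over the list alone (median −0.52, adjusted p = 0.227 with an estimated correlation), with Olig2 at −2.36 ± 0.11, Gpr17 at −2.21 ± 0.14 and Olig1 at −1.36 ± 0.16. Sox2 fell by 0.78 (SE 0.13) and Nes by 0.93 (SE 0.18), and the glioma stem cell list was not called (7 fell and 3 rose of 21, median −0.10). Among the largest rises were those of Scg2, a secretory granule protein, at least 8.32-fold, and Gem, a small GTPase that acts on the cytoskeleton, at least 4.20-fold (adjusted p = 6.78e-08 and 3.15e-08). The circadian repressor Nr1d1 rose by 3.84 ± 0.20. The heat shock genes Hspa1b and Hspa1a gave 3.85 ± 0.14 and 3.81 ± 0.15, which are near-identical copies, so that their probes may not tell them apart. The interferon-induced gene Ifit3 was at least 3.05-fold higher (adjusted p = 1.43e-05), with the same limit because of its near-identical copy Ifit3b, and the interferon response list was not called (3 rose of 18, median −0.08, mean 0.33, which differ in sign). The selenium-binding protein gene Selenbp1 was at least 5.13-fold lower (adjusted p = 1.52e-06).

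The ribosomal protein list was called higher with EHT-1864 (2 of 18 genes rose, 0 when adjusted over the list alone, median 0.21, adjusted p = 0.227 with an estimated correlation). Its median was not extreme among level-matched random lists, at percentile 94.0, and these had a median of 0.09. Not called were Rac and actin nucleation (8 of 30 fell and 2 rose, median −0.07), G2/M (4 fell and 1 rose of 24, median −0.06), G1/S (5 fell and 4 rose of 22, median 0.11, mean −0.06, which differ in sign), invasion (median 0.04), and the markers of astrocytes (median 0.02, mean −0.15, which differ in sign), neurons (median 0.05, mean 0.00), microglia and macrophages (0.26), endothelial cells (0.32) and fibroblasts and pericytes (0.19). With an estimated correlation the calls of the HIF-1, SRF and YAP, ERK and NF-kB lists held (adjusted p = 0.0405 each). In limma, 6767 probes passed, 2893 higher and 3874 lower, and 1313 of these differed at least 2-fold (246 higher, 1067 lower). Of the 6767 probes, 1593 were under the floor in both groups. The balance turned to 3705 higher and 3430 lower after median subtraction. It was near even, with 2978 higher and 3005 lower, after quantile normalization. After quantile normalization the medians of the lists for ATF4, Rac, G2/M, astrocytes and neurons had the opposite sign (0.06, 0.02, 0.04, −0.14 and −0.09), without a call. The fibroblast list was called higher with the dimmest 25% of probes left out (adjusted p = 0.0497), and the interferon list among probes above the floor on at least 3 arrays (0.0279). The ERK list was not called among probes with a log2 value of at least 6 on at least 3 arrays (adjusted p = 0.139), and neither were the Golgi (0.143), COPII (0.174) and ER (0.386) lists. The same lists were not called among probes above the floor on at least 3 arrays (adjusted p = 0.138 for ERK and Golgi, 0.172 for COPII and 0.441 for ER), and the ER list was not called with the dimmest 25% of probes left out (0.0918). Quantile normalization moved the median of the Golgi list to −0.12 and that of the autophagy list to 0.36, and without hypoxia DMSO array 1 the latter was also 0.36. The NF-kB median was 0.26 with the dimmest 25% of probes left out, and the list was still called. These totals went along with hybridization controls 0.49 higher on the EHT-1864 arrays.

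**Figure D4:**
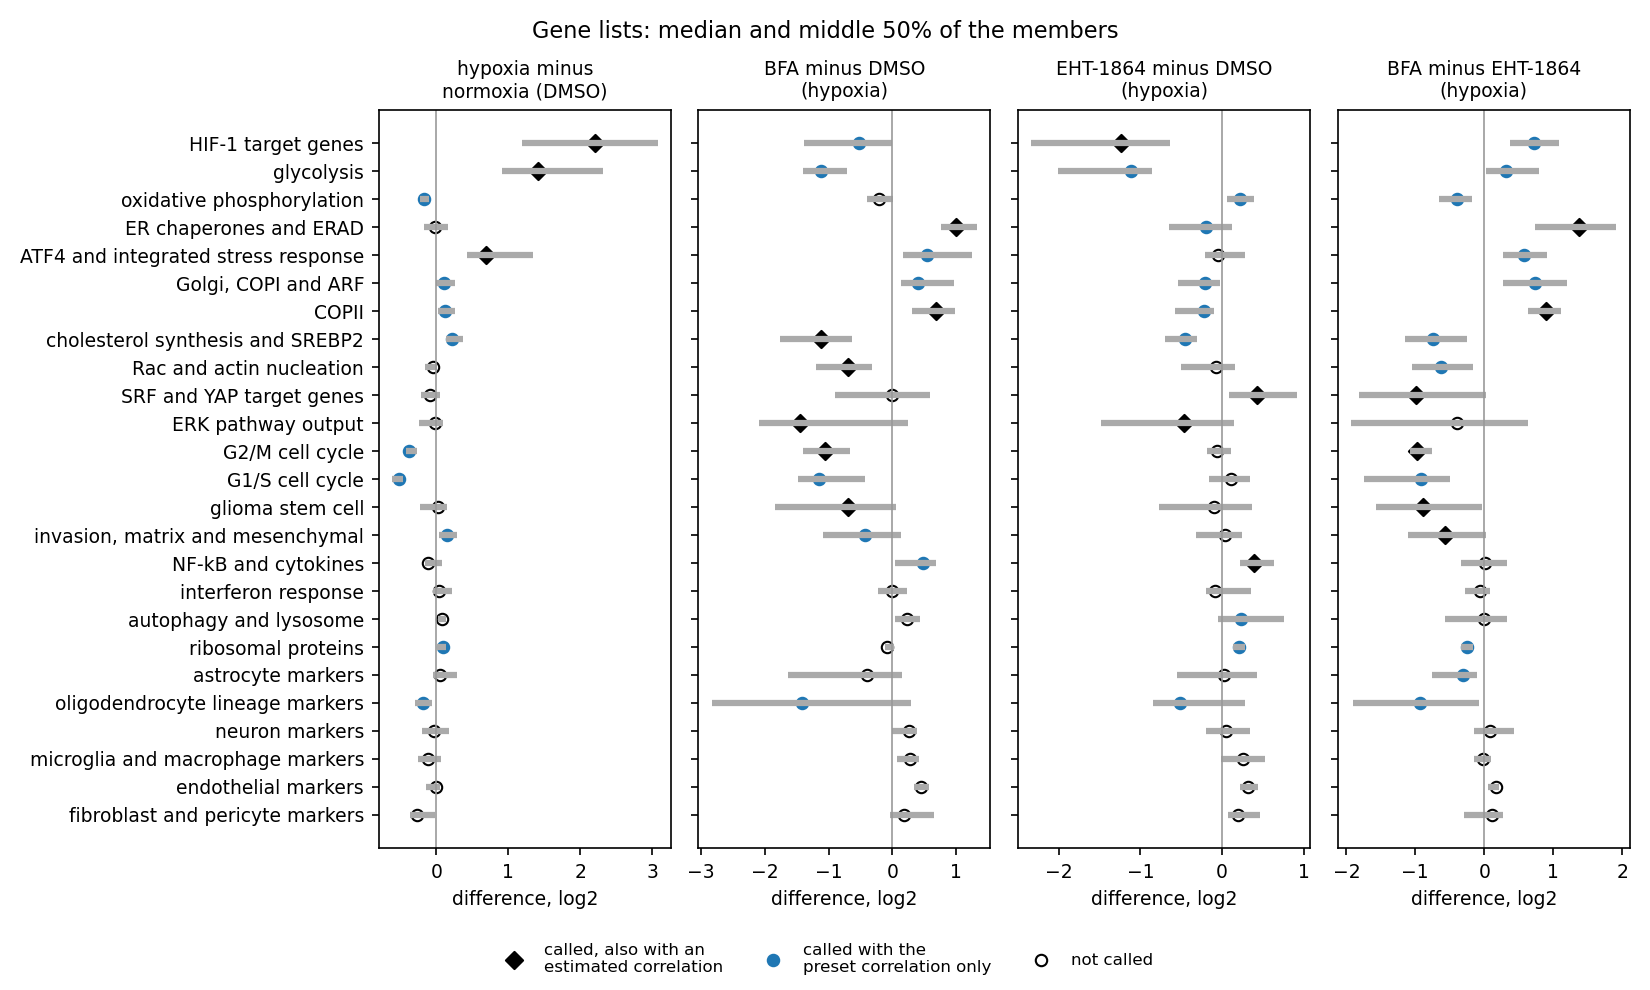
Symbols show the median log2 difference of each of 25 gene lists in the 4 comparisons and grey bars the middle 50% of the members, with black diamonds for lists called by camera (adjusted p under 0.05) also with an estimated correlation, blue circles for lists called with the preset correlation only, and open circles for lists not called. The ER list had a median of 1.01 with BFA and −0.20 with EHT-1864, and the horizontal scale differs between the panels.

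BFA and EHT-1864 were then set directly against each other in hypoxia. The compounds are not analogs of each other, and their doses match only if the BFA dose was 1 µM. Genes of the secretory pathway were higher with BFA, and cell cycle, SRF and YAP target and progenitor genes were lower. Of 25 ER chaperones and ERAD genes, 24 were higher with BFA, also when adjusted over the list alone (median 1.37, camera adjusted p = 5.80e-17). Hspa5 was higher by 1.92 ± 0.10 on the log2 scale, Hyou1, another ER chaperone, by 2.37 ± 0.13 and Creld2 by 2.46 ± 0.11. Of 19 COPII genes, 17 were higher with BFA, also when adjusted over the list alone (median 0.90), with Sec23a at 2.13 ± 0.12 and Sec24d at 2.37 ± 0.15. Of 34 Golgi, COPI and ARF genes, 22 were higher and 2 lower with BFA, or 25 and 2 when adjusted over the list alone (median 0.74, adjusted p = 0.0729 with an estimated correlation), with Kdelr3 at 2.91 ± 0.13 and Gbf1 at 1.91 ± 0.13. Of 26 ATF4 and integrated stress response genes, 15 were higher, or 16 when adjusted over the list alone (median 0.58, adjusted p = 0.151 with an estimated correlation), and Fgf21 was at least 40.1-fold higher (limma adjusted p = 1.21e-08). Ddit3 was higher with BFA by 0.83 ± 0.16.

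HIF-1 target genes were higher with BFA than with EHT-1864, 21 of 31 higher and 4 lower, or 23 and 5 when adjusted over the list alone (median 0.73, adjusted p = 0.0792 with an estimated correlation). P4ha2 differed by 2.45 ± 0.15, the ER oxidase Ero1a by 1.87 ± 0.14, Vegfa by 0.80 ± 0.20 and Slc2a1 by 0.63 ± 0.14. Of 16 glycolysis genes, 8 were higher and 1 lower, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.0221, adjusted p = 0.485 with an estimated correlation). That call ended without BFA array 2 (adjusted p = 0.0665), BFA array 3 (0.0579) or EHT-1864 array 2 (0.0512). Hif1a was lower with BFA (−0.90 ± 0.13), as was Rac1 (−0.49 ± 0.11, which did not pass after quantile normalization, adjusted p = 0.0681), and Arf1 differed by 0.26 ± 0.11 (adjusted p = 0.0719).

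Lower with BFA than with EHT-1864 were 23 of 24 G2/M genes, also when adjusted over the list alone (median −0.97), with the proliferation marker Mki67 at −1.71 ± 0.15. Of 22 G1/S genes, 17 were lower and 1 higher, or 18 and 1 when adjusted over the list alone (median −0.92, adjusted p = 0.0747 with an estimated correlation), with Mcm6 at −2.22 ± 0.13. Of 21 SRF and YAP target genes, 14 were lower and 2 higher, also when adjusted over the list alone (median −0.99), with the transgelin gene Tagln2 at −2.33 ± 0.11 and Srf at −1.87 ± 0.12. Of 30 Rac and actin nucleation genes, 20 were lower and 1 higher, or 21 and 2 when adjusted over the list alone (median −0.63, adjusted p = 0.0611 with an estimated correlation), with Wasf1 at −1.94 ± 0.14. Of 20 cholesterol synthesis genes, 14 were lower, or 14 lower and 1 higher when adjusted over the list alone (median −0.74, adjusted p = 0.0634 with an estimated correlation), with Nsdhl at −1.88 ± 0.13. Of 29 oxidative phosphorylation genes, 17 were lower, or 18 when adjusted over the list alone (median −0.40, adjusted p = 0.0634 with an estimated correlation), with the ATP synthase subunit Atp5b at −0.98 ± 0.10. The median of this list lay at percentile 18.5 of level-matched random lists, which had a median of −0.26. A shift shared with other probes of the same level was therefore not excluded for it.

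Progenitor and matrix genes were also lower with BFA. In the glioma stem cell list, 12 of 21 genes were lower and 3 higher, or 13 and 3 when adjusted over the list alone (median −0.89), with Fabp7 at −2.46 ± 0.11 and Myc at −1.75 ± 0.11. Sox2 differed by −0.89 ± 0.13 and Olig2 by −0.97 ± 0.11, while Nes was higher with BFA by 0.87 ± 0.18. In the oligodendrocyte lineage list, 10 of 16 genes were lower and 1 higher, also when adjusted over the list alone (median −0.93, adjusted p = 0.0634 with an estimated correlation), with Sox10 at −2.10 ± 0.12. In the invasion, matrix and mesenchymal list, 13 of 24 genes were lower and 2 higher, also when adjusted over the list alone (median −0.57), with the transcription factor Snai2 at −2.04 ± 0.12 and the protease inhibitor Timp3 at −2.41 ± 0.15. The astrocyte marker list was called lower (5 of 13 genes, 6 lower and 1 higher when adjusted over the list alone, median −0.31, camera adjusted p = 0.0238, adjusted p = 0.0729 with an estimated correlation), with S100b at −1.47 ± 0.13. The ribosomal list was called lower (7 of 18 genes, 8 when adjusted over the list alone, median −0.25, adjusted p = 0.131 with an estimated correlation) but not after quantile normalization (adjusted p = 0.857). Its median lay at percentile 84.9 of level-matched random lists, which had a median of −0.36. The lists for ERK output, NF-kB and cytokines, interferon response, autophagy and lysosome, neurons, microglia, endothelial cells and fibroblasts were not called (camera adjusted p = 0.0704 to 0.990), but the ERK list was called lower with a trended, robust model (0.0420).

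In limma, 8108 probes differed between the compounds, 3760 higher and 4348 lower with BFA, and 2410 of these differed at least 2-fold (903 higher, 1507 lower). Of the 8108 probes, 2235 were under the floor in both groups. With an estimated correlation the calls of the ER, COPII, SRF and YAP, G2/M, glioma stem cell and invasion lists held (adjusted p = 0.0202 to 0.0458). After quantile normalization the medians were 0.52 for glycolysis, −0.20 for oxidative phosphorylation and −0.33 for invasion, all still called. Over the members left by the filter at a log2 value of 6, the medians were −0.996 for invasion, −1.69 for the oligodendrocyte lineage and −1.31 for astrocytes, and over those above the floor on at least 3 arrays −0.99, −1.69 and −1.03. Among probes with a log2 value of at least 6 on at least 3 arrays the astrocyte and ribosomal calls ended (adjusted p = 0.0563 and 0.0759). The ribosomal call also ended among probes above the floor on at least 3 arrays (0.0727), and the astrocyte call with the dimmest 25% of probes left out (0.0592). The astrocyte median was −0.19 without BFA array 2 or without EHT-1864 array 1. Other large differences were the imprinted gene Mest at −4.03 ± 0.23, the granule protein gene Scg2, at least 4.53-fold lower (adjusted p = 1.30e-07), the prolyl isomerase Fkbp14 at 3.19 ± 0.15 and the sulfiredoxin gene Srxn1 at 3.05 ± 0.22. Mest was above the floor on 2 of 3 BFA arrays, and Fkbp14 and Srxn1 on 1 of 3 EHT-1864 arrays.

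How far the hypoxia genes moved back was followed in the 540 genes that differed in hypoxia. Of 425 genes raised by hypoxia, 291 fell with EHT-1864, 24 rose and 110 did not pass (median −0.71), and 231 fell with BFA, 91 rose and 103 did not pass (median −0.50). Of 115 genes lowered by hypoxia, 54 rose and 17 fell with EHT-1864, and 20 rose and 65 fell with BFA. This lowered set rested on all arrays: probes lower in hypoxia and higher with EHT-1864 numbered 61, but 9, 14 and 9 without hypoxia DMSO array 1, 2 or 3, and those lower in hypoxia and with BFA 69, but 13, 15 and 17. Counted over probes, 314 were higher in hypoxia and lower with EHT-1864, against 81.6 from independent lists. For BFA 252 were higher in hypoxia and lower with the compound, against 115. Simulated unchanged groups compared with the same controls gave 0 in both cases, but such groups yield next to no calls, so that this count is no measure of the overlap, and the value for independent lists leaves out the shared controls. It also leaves out level, so part of the excess may come from level. Of the probes higher in hypoxia, 401 lay above the median level and 67 below it. Of those lower with BFA, 4751 lay above it and 719 below, and with EHT-1864 3329 and 545. The hypoxia DMSO arrays enter both sides of these overlaps and are too few to be split into parts of at least 2 arrays each, so part of the excess over independent lists may come from the shared controls. For genes picked as raised with 1 of these arrays, the EHT-1864 change against the others had medians of −1.42 to −1.36. That split covers only genes raised enough to be picked with 1 array, and it was not made for BFA. The overlap for EHT-1864 was 178, 181 and 182 without hypoxia DMSO array 1, 2 or 3, and that for BFA 136, 143 and 141. Across probes, the covariance of the hypoxia change with the EHT-1864 change differed from the simulated covariance by −0.0519 (r = −0.430 against −0.4996 simulated), and with the BFA change by −0.0255 (r = −0.184 against −0.5002).

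The BFA and EHT-1864 changes, which share the same DMSO arrays, were called higher in both for 1573 probes (755 from independent lists) and lower in both for 2468 (954). The same limits hold for these values, with 0 simulated in each case, and part of the excess over independent lists may come from the shared controls. Their covariance exceeded the simulated one by 0.201 (r = 0.542 against 0.5004 simulated). The simulated groups held no change that varies with level. On the deposited values, called probes above the median level were mostly lower with BFA (4751 lower, 2111 higher) and with EHT-1864 (3329 lower, 1657 higher). How much of the excess comes from this common shift was not tested. Without hypoxia DMSO array 1, 2 or 3 the probes higher in both numbered 1002, 1139 and 954, and those lower in both 1947, 2026 and 1935.

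Each compound group in hypoxia was also compared with normoxia and DMSO, where oxygen and compound both differ. Of 31 HIF-1 target genes, 26 were higher with BFA in hypoxia than in normoxia (median 1.07), and 14 were higher, 3 lower and 14 not past the test with EHT-1864 (median 0.53). Of 16 glycolysis genes, 9 were higher and 2 lower with BFA (median 0.51), and 3 were higher and 13 not past the test with EHT-1864 (median 0.12). The counts of genes higher with BFA include some under the floor in both groups. These were Car9, Adm, Car12, Angptl4 and Lox among the HIF-1 targets and Slc16a3 among the glycolysis genes. P4ha2 lay 2.79 ± 0.15 above normoxia with BFA and 0.35 ± 0.15 with EHT-1864 (limma adjusted p = 1.45e-08 and 0.113). Pdk1 lay 2.40 ± 0.25 and 0.52 ± 0.25 above it (adjusted p = 5.92e-06 and 0.168), Ndrg1 4.13 ± 0.16 and 2.92 ± 0.16, and Vegfa 2.74 ± 0.20 and 1.93 ± 0.20.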

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

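No test in this part was chosen only after its result was seen, and the predictions were written before each test was run. Groups of 3 arrays were not tested for single outlying arrays.

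Several kinds of control probes were higher on the compound arrays than on the DMSO arrays in hypoxia, which is a signal outside the probes used for the comparisons. Whether the neg control probes detect some RNA of the cells was not tested. On the log2 scale the hybridization controls were higher by 1.17 with BFA and 0.49 with EHT-1864, the background probes by 0.50 and 0.35, the neg control probes by 0.30 and 0.12, and the ERCC probes by 0.43 and 0.28. The poly-A controls were higher by 0.61 with BFA. In each of these cases all 3 compound arrays lay above all DMSO arrays of both oxygen levels, and the two-sided exact permutation p was 0.1, which is the smallest that 3 against 3 arrays allow. The poly-A controls differed by 0.30 with EHT-1864 (exact p = 0.4), and the pos control probes by 0.00 with BFA and −0.13 with EHT-1864.

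With BFA, the called probes under the median level were mostly higher (3688 higher, 719 lower) and those above it mostly lower (4751 lower, 2111 higher). From the dimmest to the brightest 25% of probes the median log2 change was 0.29, 0.36, −0.21 and −0.27. A weaker signal of cell RNA on these arrays, which the higher control probes could come from, would give such a slope. After another quantile normalization, 1617 probes of the dimmer part of the array were called higher against 3688 before, or 43.8%, which lies between the bounds set for and against that explanation. In that part 1128 were then called lower. In the brighter part 3553 were then called higher and 3199 lower, so the calls there were no longer mostly lower. The bounds did not cover the brighter part. A weaker signal and a change in the cells cannot be told apart here for these probes, because both follow the same groups.

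HIF-1 target genes were lower with EHT-1864 than with DMSO in hypoxia. A weaker signal would move random lists of the same level alike, but the median of this list lay at percentile 0 of 10000 level-matched lists, and after another quantile normalization the list stayed called (median −1.10, camera adjusted p = 7.43e-15, with 1.66e-17 to 0.0405 over the alternatives that keep all arrays). Chance values shared through the DMSO arrays were also argued against: for genes picked as raised with 1 hypoxia DMSO array, the median EHT-1864 change against the other DMSO arrays was −1.36 at its highest over the 3 choices of the array. An effect of the compound on these genes may therefore be followed up as a hypothesis, found and tested on the same data.

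Glioma stem cell and oligodendrocyte lineage genes were lower with BFA. As fixed, these lists share Olig1, Olig2 and Pdgfra, so they are not independent of each other. The higher of the percentiles of their medians among level-matched random lists was 0.15, which argues against a weaker signal of cell RNA as the whole cause. After another quantile normalization both lists stayed called (median −0.41, camera adjusted p = 5.01e-05, and median −1.17, adjusted p = 9.15e-06), and over the alternatives that keep all arrays the highest adjusted p was 0.0264 for the glioma stem cell list and 0.0849 for the oligodendrocyte list, the latter with an estimated correlation. A loss of progenitor gene expression with BFA may be followed up as a hypothesis, and toxicity at the dose used, which the labels leave unsettled, was not tested.

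The arrays of each comparison were also regrouped. The 10 splits of 6 arrays are too few for a share under 0.05, and 1 of the 10, the real one, gave as many probes in each comparison. The real splits called 593 probes for hypoxia, 11269 for BFA, 6767 for EHT-1864 and 8108 between the compounds, and the highest of the other splits called 0 in each. Each other split mixes arrays of both groups, which puts any real difference between them into the spread. Few calls were therefore bound to follow there, and no conclusion is drawn from these counts.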

How the results depend on the processing

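The filter on the neg control level was the only alternative chosen after the data were seen. No list or named gene changed direction past its threshold. The balance of all called probes did turn in places. The share higher went from 42.8% to 51.9% for EHT-1864 after median subtraction. For BFA it went from 51.5% to 30.5% with a log2 value of at least 6 on at least 3 arrays. Over all alternatives and left-out arrays, list results stayed on their side of the threshold in 562 of 593 cases for hypoxia, 554 of 593 for BFA, 564 of 593 for EHT-1864 and 570 of 593 between the compounds, lost the call in 24, 17, 20 and 19 and gained one in 7, 22, 9 and 4. Named genes stayed on their side in 1211 of 1329, 1431 of 1439, 1394 of 1421 and 1673 of 1690 cases, lost the call in 77, 0, 19 and 10 and gained one in 41, 8, 8 and 7. Signal over background limited the dim probes, since 65.2% of probes lay below the floor with BFA.

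The hypoxia count of 593 probes became 1264 with a log2 value of at least 6 on at least 3 arrays, 1247 with the neg control filter, 1221 with a trended, robust model, 2258 with array weights and 1234 with the 6 compared arrays alone, and the share higher moved from 78.9% to 61.7% with the log2 filter and 56.0% with array weights. It was 175 with a log2 change of at least 1 and 238 at the stricter adjusted p, and it ranged from 254 to 898 with an array left out (273, 287 and 284 without hypoxia DMSO array 1, 2 or 3, 315, 282 and 254 without normoxia array 1, 2 or 3, and 898 without BFA array 1). The BFA count of 11269 became 7215 and 7423 with the filters on level and 3235 with a log2 change of at least 1 (9538 to 11394 with an array left out). The EHT-1864 count of 6767 became 1313 with that change and 3796 at the stricter adjusted p (4986 to 7806). The count between the compounds, 8108, became 2410 with that change (6900 to 8280). Stricter thresholds and fewer arrays or probes lower or shift such counts by construction, and for the variance models and array weights the cause was not tested. Quantile normalization gave 567, 9497, 5983 and 7966 probes, of which 490, 7612, 4984 and 6882 were also called before.

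Of 12, 15, 13 and 17 called lists, 3, 7, 4 and 6 were called with an estimated correlation. The fry test, which does not compare a list with other genes, called 13, 21, 20 and 20. With an array left out the numbers ranged from 10 to 13, 15 to 17, 13 to 13 and 16 to 17. Same-numbered arrays did not deviate together (r from −0.180 to 0.170, above 0.1 in 1 of 18 pairs), so the numbers were not taken as pairs. With the replicate number as a block, 442, 10938, 6349 and 7816 probes were called, 426, 10723, 6162 and 7650 of them without the block too, and 12, 15, 13 and 17 lists.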

Other observations

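The gene lists for the hypotheses below were prompted by genes seen to change, which were left out of them, and their tests were set before the list values were seen. The genes of the opening paragraphs were chosen after their values were seen, and each passed in the same direction after another quantile normalization and after median subtraction.

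Matrix and mesenchymal genes moved both ways with EHT-1864 in hypoxia. Snai2, a transcription factor of mesenchymal cells, rose by 2.29 ± 0.12 on the log2 scale (limma adjusted p = 9.40e-08, n = 3), Fn1 by 1.59 ± 0.20 and the hyaluronan receptor Cd44 by 1.33 ± 0.14, and Tgfbi, a secreted matrix protein, was at least 4.20-fold higher (adjusted p = 1.12e-06). The integrin Itgav fell by 1.29 (SE 0.11), Cdh2 by 0.79 (SE 0.17) and Tnc by 0.73 (SE 0.16). Of the 24 measured genes of the invasion, matrix and mesenchymal list, 5 rose and 4 fell. The G1/S list moved apart in the same way, with Mcm4 and Mcm2, subunits of the replicative helicase, up by 0.81 ± 0.16 and 0.52 ± 0.14, and cyclin E2 (Ccne2) down (−1.61 ± 0.16, with 1 of 3 EHT-1864 arrays above the floor). Aurkb, a kinase of mitosis, fell by 0.96 (SE 0.13).

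Genes of the integrated stress response also went in different directions with EHT-1864. Atf3 rose by 2.28 ± 0.13 (adjusted p = 2.36e-07) and Ddit3 by 1.66 ± 0.16, while Slc7a11 fell by 1.66 (SE 0.18, with 2 of 3 EHT-1864 arrays above the floor) and Vldlr by 1.27 (SE 0.17). With BFA, Slc7a11 rose by 1.28 ± 0.18 (adjusted p = 9.43e-05), and it was higher with BFA than with EHT-1864 by 2.93 ± 0.18. Among HIF-1 target genes, Hilpda, a lipid droplet protein, and Ero1a rose with BFA, by 0.68 ± 0.12 and 0.47 ± 0.14, while the median of the list was −0.52 (adjusted p = 0.199 with an estimated correlation). The neuronal and progenitor gene Map2 fell by 1.92 with BFA (SE 0.12, adjusted p = 5.25e-08).

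The rise of Hspa1a and Hspa1b with EHT-1864 raised the hypothesis of a wider heat shock response. Of 13 other measured heat shock genes, 3 rose and none fell, and the median was 0.11, at percentile 85.7 of level-matched random lists (camera adjusted p = 0.323), so a wider response was not borne out.

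Scg2, Gem and Nr1d1, which rose with EHT-1864, are known targets of CREB, so a CREB response was tested as a hypothesis on 14 other measured targets. The targets Bdnf and Ppargc1a, which also rose, were left out of the list as well. The median was 0.20, at percentile 97.55 of level-matched random lists, 5 genes rose and 3 fell, and camera did not call the list (adjusted p = 0.119, or 0.320 with an estimated correlation and 0.0452 after another quantile normalization). The percentile and the list test went different ways, so a CREB response may be present and stays open.

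Srxn1 was higher with BFA than with EHT-1864, and Slc7a11 rose with BFA, which raised the hypothesis of an NRF2 response to BFA. Hmox1, a target that rose with BFA by 1.93 ± 0.13, was left out of the list with them. Of the 15 other measured NRF2 targets, 10 were lower, 1 was higher and 4 did not pass, with a median of −0.69 at percentile 1.65 of level-matched random lists (camera adjusted p = 0.00790, or 0.320 with an estimated correlation). A rise of these targets together was not borne out. With EHT-1864 the median of this list was −0.53, with 8 genes lower and 2 higher (camera adjusted p = 0.0463, or 0.320 with an estimated correlation), and the difference between the compounds was not tested for this list.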
